A study of Mus musculus with 9 samples.

How the data were processed

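Total RNA of mouse peritoneal macrophages from male animals was measured on 9 Agilent 1-colour arrays labelled with Cy3, with 3 arrays in each of 3 groups. The macrophages had been sorted as CD45+ F4/80+ cells by flow cytometry, per the labels' protocols. Group Ctrl was cultured alone for 24 h, group T was co-cultured with CT-26 cells for 24 h, and group M holds migratory macrophages from the upper Transwell chamber of a co-culture with CT-26 cells, whose duration is not given in the sources used here. Groups were taken from the sample titles. No label states that the arrays of a group came from separate cultures or animals, so p-values measure only the spread between these samples, which may be technical.

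The authors scanned the arrays and extracted spots with Agilent Feature Extraction 10.7.3.1, per the submitters' processing notes. Each deposited scanner file gives a processed signal intensity per spot, background-subtracted and detrended but not scaled between arrays, per the file headers. The files name each probe's position on mouse build mm9, and positions are given as the files state them. A deposited value table of the same arrays holds 55821 probes without a stated scale, and each of its columns was set against all 9 scanner files. The deposited columns for Ctrl1, M1, M2 and M3 were on a linear intensity scale, with medians of 215, 195, 246 and 219. The deposited columns for Ctrl2, Ctrl3, T1, T2 and T3 were on a log2 scale with the array's 75th percentile at about 0, and their medians were -3.39, -3.71, -3.76, -3.93 and -4.03. Within a tolerance of 0.001 on the log2 scale and up to a constant, 6 columns equalled their own scanner file, the M1 and M2 columns equalled each other's file, and the T2 column equalled none. The scale and centring of the table were found in this way for 8 columns, and those of the T2 column stay inferred from its values alone. The direction is not in question, since no column is a ratio.

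Every array had 62976 spots, of which 59305 were not controls and represented 55681 probes. Control spots and spots marked as outliers were left out, which removed between 147 and 299 spots per array. No spot was saturated. Spots of a probe were averaged, log2 of the processed signal was taken, and the array's 75th percentile was subtracted. Probe accessions were matched without version to a reference gene table of assembly GRCm38.p6, used for names only, which named 26762 probes, and 6488 kept the array's own gene name. The remaining 22431 probes carried no gene symbol and were counted apart. A probe was tested where it was well above background on all 3 arrays of at least 1 group, and the probe with the highest mean over the 9 arrays stood for its gene, which left 18537 genes and 15061 unnamed probes.

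Group means were fitted to all 9 arrays together with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), and the contrasts T minus Ctrl, M minus Ctrl and M minus T were tested with Benjamini-Hochberg adjustment at an adjusted p of 0.05. Adjusted p-values of genes come from this test throughout. The SE given with a log2 difference is the moderated SE of this fit, which pools the spread of all 9 arrays. It is therefore the same in each contrast of a gene and is not the SE of the compared groups alone. Where the arrays of a group varied widely, it may be too small. The F test over the 3 groups used the same fit. Where a gene's probe was not well above background on any array of a group, the fold is a bound written "at least N-fold". The bound sets the bright group's mean against the dim group's mean of, per array, the higher of the lowest signal among probes well above background and the dim probe's own signal.

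Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, and again with an estimated correlation. Of the 40 lists, 39 had the minimum of 5 tested members. The lists covered macrophage identity and activation, signalling and stress responses, metabolism, migration and matrix genes, and markers of other cells that a peritoneal sort could hold. The groups, contrasts, lists, naming rule and first set of alternatives were fixed before the data were examined. The naming rule took, per contrast, the 8 largest rises and 8 largest falls among genes past the threshold whose arrays did not overlap between groups, passing over clone and model names. It also took up to 4 called members of each list that camera called and of each list of other-cell markers, and the sort markers and a short set of macrophage genes fixed in advance. Members that moved against the rest of their list, and others outside the rule, were named after their values were seen.

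The procedure was tested on simulated data built from the real arrays, with 200 changed genes. For T against Ctrl over 18537 genes, genes lowered 2 log2 units were recovered at 100% and genes raised 2 units at 96%, against 36% and 38% at 1 unit. That step made 147 calls, of which 12 (8.16%) were false, above the nominal rate. For M against Ctrl the recovered shares at 1 unit were 42% lowered and 50% raised, and for M against T they were 32% and 34%, and 4 of 147 calls (2.72%) and 1 of 130 (0.769%) were false. The simulation drew independent noise with 1 spread per gene for all groups, and changed 200 of 18537 genes. The real groups differed in spread, and the real T against Ctrl called 45.0% of genes. The recovered and false shares may thus not carry over to the real comparisons. The number of arrays limits the precision, since 3 per group leave few degrees of freedom for each gene.

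The alternatives were quantile normalization, median scaling, normexp background correction with an offset of 50, other filters on dim probes, the mean of a gene's probes, fits of 2 groups only, a trended and robust variance, array weights, the replicate number as a block, slide and scan blocks, the deposited value table, and leaving out each array. Alternatives added after the data were seen were the value table without its T2 column, leaving out M1 and M3 together, and leaving out Ctrl1 and Ctrl2 together. All arrays of Ctrl and M lay on 1 slide and those of T on another, so a slide or scan block could be fitted for M against Ctrl only. Same-numbered arrays were not treated as pairs, since their deviations from the group means did not correlate in all comparisons. Some results on marker detection are not reported here. Figures were drawn with matplotlib 3.10.9.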

Results

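RNA levels were measured in mouse peritoneal macrophages that had been cultured alone (Ctrl), co-cultured with CT-26 cells, a mouse colon carcinoma line (T), or recovered as migratory macrophages from the upper chamber of a Transwell co-culture with CT-26 cells (M). A Transwell is a well divided by a porous membrane that cells can cross. Each group had 3 arrays. The share of probes well above background was 78.0%, 78.7% and 69.97% on Ctrl1 to Ctrl3, 72.3%, 70.9% and 66.2% on T1 to T3, and 60.5%, 66.6% and 63.2% on M1 to M3. The net signal of the negative controls was highest on M1 (59.2) and M3 (45.8), and lay between 24.2 and 36.4 on the other arrays. Replicate spots varied with a median coefficient of variation of 19.7% on M1 and 26.6% on M3, and of 5.63% to 13.1% on the others. The median SD of a gene between arrays was 0.31 in Ctrl, 0.17 in T and 0.22 in M on the log2 scale. Ctrl3 correlated more closely across probes with M2 (r = 0.977) than with Ctrl1 (r = 0.969) and most closely with Ctrl2 (r = 0.981), while Ctrl1 and Ctrl2 correlated at 0.991. The first principal component held 52.0% of the variance and placed the Ctrl arrays (-109.9 to -32.6) below the M arrays (-0.458 to 29.6) and the T arrays (38.5 to 71.3). The second held 29.2% and set the M arrays (-57.5 to -66.0) against the T arrays (41.9 to 46.8).

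The comparison of T with Ctrl asked what differed in macrophages after 24 h with carcinoma cells. Csf3, which encodes the granulocyte growth factor G-CSF, rose 60.7-fold (log2 difference 5.92 ± 0.17, SE, n = 3 per group), and Csf1, the macrophage growth factor, rose 34.4-fold (5.11 ± 0.18). The neutrophil chemoattractant Cxcl2 rose 25.6-fold (4.68 ± 0.28) and the placental growth factor gene Pgf rose 21.7-fold (4.44 ± 0.18). P4ha2, a subunit of the enzyme that hydroxylates collagen prolines, rose 28.5-fold (4.83 ± 0.19). On mm9 the Csf3 probe lies on chromosome 11 from 98564614 to 98564673, the Csf1 probe on chromosome 3 from 107544333 to 107544392, and the P4ha2 probe on chromosome 11 from 53945032 to 53945091. In every gene that the naming rule took as passing the test, in this and the other comparisons, the arrays of the compared groups did not overlap. The rule itself required this of the largest rises and falls.

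Several genes were not well above background on any Ctrl array. The macrophage elastase gene Mmp12 was at least 16.4-fold higher in T, the collagen gene Col2a1 at least 18.6-fold, the thrombomodulin gene Thbd at least 15.3-fold and the secreted signalling gene Wnt9a at least 22.7-fold. Gstt4, a glutathione transferase gene, rose 43.8-fold (5.45 ± 0.23) and was well above background on 1 of 3 Ctrl arrays. Aknad1 was at least 28.1-fold higher by its brightest probe, and its other tested probe went the other way. The largest falls belonged to genes whose Ctrl arrays varied widely. Jakmip2 fell by 3.70 ± 0.61 on the log2 scale, with Ctrl at 0.96 ± 1.59 (SD) and T at -2.75 ± 0.16. Nebl fell by 3.68 ± 0.93 and Pla2g2c by 4.57 ± 1.14, with Ctrl SDs of 2.25 and 2.73. Olfr1218 fell by 4.70 ± 1.22, Olfr1250 fell by 3.49 ± 0.66, and Tek, which encodes an angiopoietin receptor, fell by 3.51 ± 0.89. These 3 and Pla2g2c were well above background on 1 or 2 of the 3 T arrays. Without Ctrl1 and Ctrl2 the calls of Olfr1218, Nebl, Tek, Pla2g2c and Olfr1250 ended (adjusted p 0.336, 0.300, 0.293, 0.260 and 0.0550). Cap2 fell by 3.67 ± 1.05, and 5 of 22 other settings ended its call (adjusted p up to 0.508). Has2, a hyaluronan synthase gene, was at least 3.06-fold lower in T.

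Immediate early genes, which respond within minutes to many stimuli, rose as a group in T. Of 32 tested members 25 rose and 1, Egr3, fell (26 and 1 adjusted over the list alone), with a list median of 1.16, and camera gave an adjusted p of 1.72e-11 (adjusted p = 0.127 with an estimated correlation). Myc rose by 3.57 ± 0.21, Fosl1 by 2.86 ± 0.19, Egr2 by 2.83 ± 0.19 and Dusp5 by 2.84 ± 0.21. Of 37 hypoxia and glycolysis genes 20 rose (21 adjusted over the list alone) and 17 did not pass. Besides P4ha2, the oxygen-sensing hydroxylase genes Egln3 and Egln1 rose by 1.62 ± 0.17 and 1.85 ± 0.22. Camera's adjusted p was 7.17e-05 (adjusted p = 0.436 with an estimated correlation). Of 25 angiogenic and growth factors 14 rose and 4 fell (15 and 4 adjusted over the list alone; camera adjusted p 3.29e-05, adjusted p = 0.241 with an estimated correlation). Areg rose by 3.67 ± 0.19 (2 of 3 Ctrl arrays above background), Hbegf by 2.44 ± 0.17 and Vegfa by 1.24 ± 0.16, while Vegfb, Fgf2, Gas6 and Tek fell.

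Lists of both classical and alternative macrophage activation were called higher in T at the preset correlation. Of 24 inflammatory genes 13 rose and 1, Il12b, fell, the same numbers as when adjusted over the list alone (camera adjusted p 3.35e-05, adjusted p = 0.127 with an estimated correlation). Acod1, which makes the metabolite itaconate, rose by 3.50 ± 0.16, Il1b by 3.12 ± 0.24 and the cyclooxygenase gene Ptgs2 by 2.21 ± 0.21. Nos2, the inducible nitric oxide synthase gene, differed by 0.39 ± 0.25 and did not pass. Of 29 alternative activation genes 16 rose and 5 fell (16 and 6 adjusted over the list alone; camera adjusted p 0.00107, adjusted p = 0.127 with an estimated correlation). Arg1, the arginine-degrading enzyme, rose by 3.95 ± 0.19 (2 of 3 Ctrl arrays above background) and Ccl2, a monocyte chemoattractant, by 2.82 ± 0.19, whereas Chil3, Chil4, Cd163, Pdcd1lg2 and Alox15 fell. Of 36 interferon-stimulated genes 21 rose and 1, Ifit2, fell (22 and 2 adjusted over the list alone; camera adjusted p 7.69e-06, adjusted p = 0.400 with an estimated correlation), among them Cmpk2 by 2.74 ± 0.26 and Oasl2 by 2.16 ± 0.24. Of 34 NF-kB targets 18 rose and 1, Cxcl1, fell, as they did adjusted over the list alone (camera adjusted p 7.69e-06, adjusted p = 0.325 with an estimated correlation). Lcn2, an iron-siderophore binding protein gene, rose by 2.94 ± 0.15.

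Some lists tied to movement and matrix were also called in T, whereas those of actin cytoskeleton and extracellular matrix genes were not (camera adjusted p 0.927 for both). Of 26 chemoattractant ligands 11 rose, and Cxcl1, Cxcl12 and Cx3cl1 fell (13 and 6 adjusted over the list alone; camera adjusted p 0.00435, adjusted p = 0.327 with an estimated correlation). Of 28 chemoattractant receptors 12 rose and 3, Ccr8, Cxcr1 and Csf2rb, fell (13 and 4 adjusted over the list alone; camera adjusted p 0.00569, adjusted p = 0.403 with an estimated correlation). Ptafr, the platelet-activating factor receptor, rose by 1.97 ± 0.19 and Cxcr4 by 1.92 ± 0.21, a call that ended in 1 of 23 other settings for Cxcr4. Of 30 integrins and adhesion receptors 12 rose and 2, Itga1 and Itgb3, fell, equally over the list alone (camera adjusted p 0.0374, adjusted p = 0.781 with an estimated correlation). Of 29 matrix proteases and inhibitors 10 rose and 6 fell, equally over the list alone (camera adjusted p 0.0463, adjusted p = 0.781 with an estimated correlation). The gelatinase gene Mmp9 rose by 3.43 ± 0.16 (2 of 3 Ctrl arrays above background) and the plasminogen activator gene Plat by 2.79 ± 0.17, and the members that fell were Mmp8, Mmp14, Mmp27, Timp2, Timp3 and Adam19. Of 23 other settings 10 ended the call of the proteases (adjusted p up to 0.423), 4 that of the integrins (up to 0.0996) and 2 that of the ligands (up to 0.112).

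At the preset correlation camera called the lists of checkpoint genes, phagocytic receptors and TGF-beta targets higher in T, and that of cell cycle genes lower. Of 30 checkpoint and T cell suppression genes 13 rose and 4, Pdcd1lg2, Ido2, Siglece and Tnfrsf14, fell (13 and 5 adjusted over the list alone; camera adjusted p 0.00107, adjusted p = 0.177 with an estimated correlation). Nt5e, the CD73 ectonucleotidase gene, was at least 4.71-fold higher and Arg2 rose by 2.31 ± 0.17, and Cd274, which encodes PD-L1, differed by 0.43 ± 0.36 and did not pass. Of 34 scavenger and phagocytic receptors 13 rose and 4, Marco, Cd163, Tyro3 and Cd300ld, fell, equally over the list alone (camera adjusted p 0.0155, adjusted p = 0.504 with an estimated correlation), and Mertk, an apoptotic cell receptor, rose by 2.74 ± 0.20. Of 22 TGF-beta targets 12 rose and 4, Ltbp1, Itgb6, Itga1 and Cdkn2b, fell, equally over the list alone (camera adjusted p 0.00257, adjusted p = 0.177 with an estimated correlation), and Smad7, an inhibitor of the pathway, rose by 2.52 ± 0.24. Of 49 cell cycle genes 24 fell and 2, Ccne1 and Cdc6, rose (26 and 2 adjusted over the list alone), with a list median of -0.47 (camera adjusted p 0.00750, adjusted p = 0.781 with an estimated correlation). Median scaling of the arrays ended this call (adjusted p 0.191). The mitotic genes Bub1b and Kif20a fell by 1.16 ± 0.16 and 0.89 ± 0.15, and the call of Kif20a ended under median scaling and with the deposited value table (adjusted p up to 0.108).

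The sort markers Ptprc (CD45) and Adgre1 (F4/80) differed between T and Ctrl by 0.01 ± 0.20 and 0.09 ± 0.22 and did not pass. Beside the lists above, markers of other cells moved in both directions. Of 17 carcinoma epithelium markers 7 rose and 5 fell (7 and 7 adjusted over the list alone; camera adjusted p 0.445). Krt19, an epithelial keratin gene, rose by 3.62 ± 0.27, Areg by 3.67 ± 0.19 and Elf3 by 1.45 ± 0.18, whereas Epcam, Krt7, Cldn4, Ocln and Lgals4 fell and Krt18 differed by -0.11 ± 0.18 without passing. The Elf3 call ended in 1 of 23 other settings. Of 21 granulocyte markers 6 rose and 8 fell (7 and 10 adjusted over the list alone), with S100a8 up by 3.05 ± 0.22. Of 18 T and NK cell markers 3 rose and 8 fell (4 and 10 adjusted over the list alone), and Cd3g fell by 1.75 ± 0.30 (2 of 3 T arrays above background).

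In all, 3195 genes were higher and 5151 lower in T than in Ctrl among 18537 tested (limma), of which 1743 and 3227 changed at least 2-fold. The arrays of the groups did not overlap for 53.4% of genes, against 10% by chance, and of the unnamed probes 1445 were higher and 6266 lower. The split between higher and lower depended on the scaling. The share of calls that were higher was 38.3%, against 51.8% under quantile normalization and 65.8% under median scaling, and the median of all genes shifted from -0.15 to 0.00 and 0.28 on the log2 scale. In the fifth of genes with the dimmest probes 79.0% of calls were lower. Without T2 or T3, 3426 and 3322 genes were lower. Of 98 named genes called here 31 lost their call in some other setting, 11 with the deposited value table and 6 with a single array left out, namely Cap2, Cx3cr1, Ebf1, Efemp1, Msln and Pou2af1. All T arrays lay on a slide and scan of their own, so T and slide cannot be told apart in any comparison with T.

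**Figure D1:**
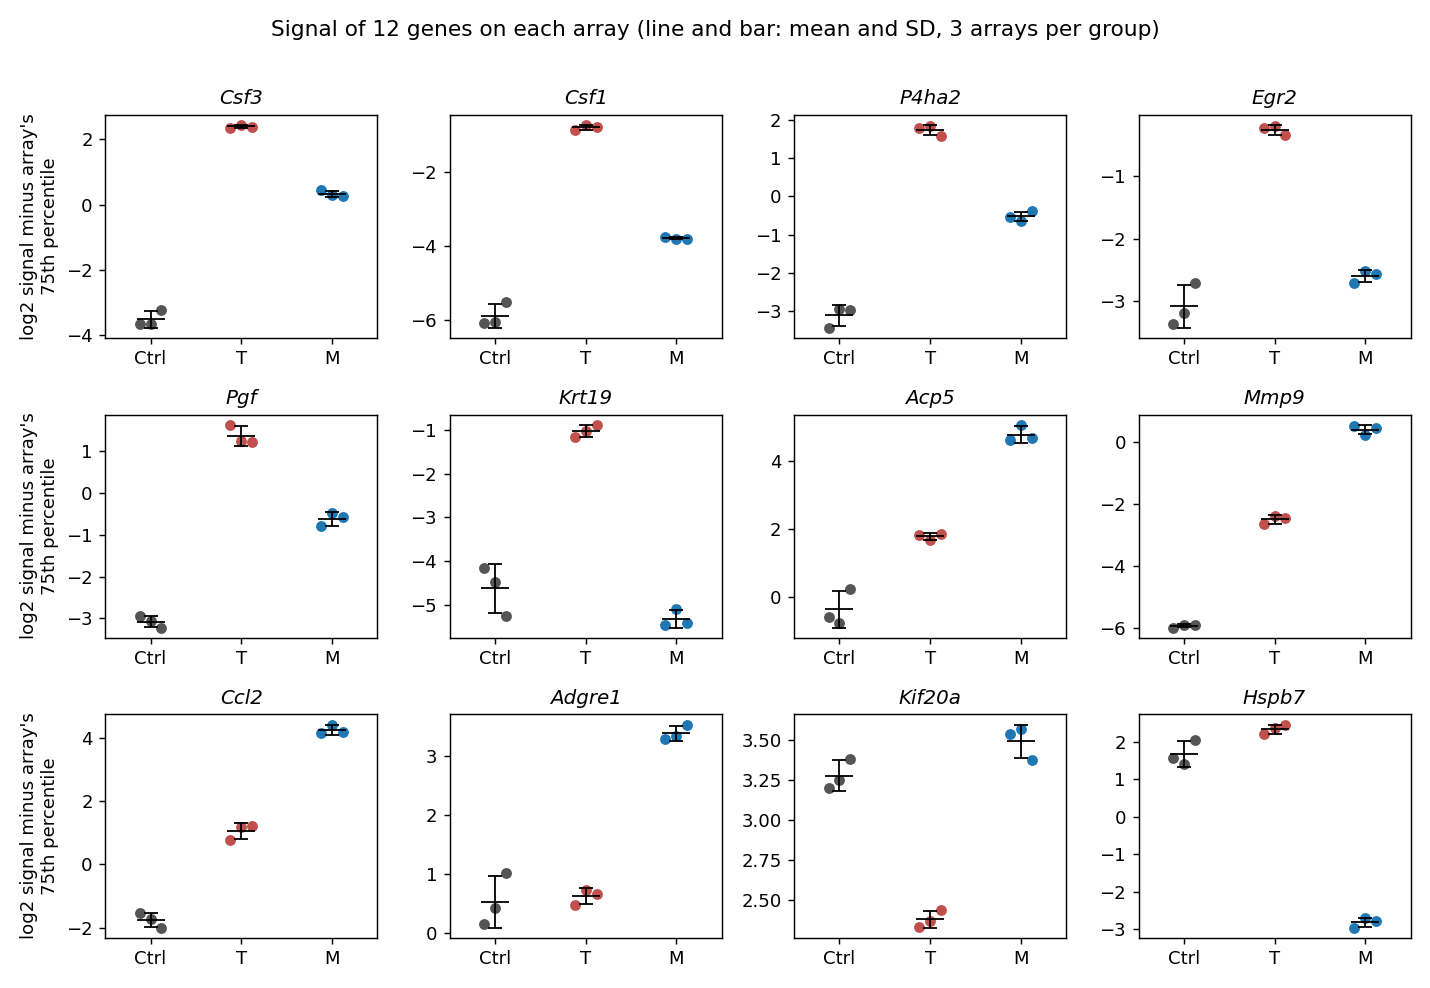
Signal of 12 genes on each of the 9 arrays, as log2 of the processed signal minus the array's 75th percentile, with 1 point per array and lines for the mean and SD of each group of 3. Csf3 means were -3.52 in Ctrl, 2.40 in T and 0.33 in M, and Ccl2 means were -1.76, 1.06 and 4.25, with each panel on its own axis, and Acp5 was chosen after its values were seen.

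The comparison of M with Ctrl asked what differed in migratory macrophages from the co-culture. The sample titles, descriptions and protocol call M the migratory macrophages, whereas the cell type label gives that description to the T samples, and groups follow the titles here for every value involving T or M. Ctsk, which encodes the collagen-degrading protease cathepsin K, was at least 739-fold higher in M and not well above background on any Ctrl array. Atp6v0d2, a proton pump subunit gene, was at least 161-fold higher, and the transcription factor gene Tfec at least 33.3-fold. Mmp9 rose 80.3-fold (6.33 ± 0.16, SE, n = 3 per group, 2 of 3 Ctrl arrays above background), Ccl2 64.7-fold (6.01 ± 0.19) and Ppfibp2 117-fold (6.87 ± 0.27). On mm9 the Ctsk probe lies on chromosome 3 from 95313165 to 95313224, the Mmp9 probe on chromosome 2 from 164780620 to 164780679, and the Ccl2 probe on chromosome 11 from 81850650 to 81850709. Plpp3, a lipid phosphatase gene, was at least 25.1-fold higher. Slc9b2, a sodium and proton exchanger gene, and the chemokine receptor gene Ccr1 rose by 8.15 ± 0.32 and 6.90 ± 0.56, each well above background on 1 of 3 Ctrl arrays, and Adh7 rose by 6.93 ± 0.29 (2 of 3).

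The membrane protein gene Tmem26 fell by 5.16 ± 0.25 in M and was well above background on 2 of 3 M arrays. Hspb7, a small heat shock protein gene, fell by 4.49 ± 0.20, the RNA-binding protein gene Igf2bp1 fell by 4.35 ± 0.25, and Pxdn, which encodes peroxidasin, fell by 4.07 ± 0.24. Gdpd3 fell by 3.91 ± 0.28, and Pip5k1b by 3.74 ± 0.83 (2 of 3 M arrays above background), a call that ended without M3 and without M1 and M3 together (adjusted p up to 0.347). Pla2g2c fell by 4.02 ± 1.14 with a Ctrl SD of 2.73, and Cap2 was at least 10.5-fold lower with a Ctrl SD of 2.71. These last calls ended in 9 and 6 of 24 other settings (adjusted p up to 0.603 and 0.371).

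The list of alternative activation genes was called higher in M at the preset correlation. Of 29 tested 15 rose and 2, Cd163 and Pparg, fell (17 and 3 adjusted over the list alone), with a list median of 1.14 (camera adjusted p 7.22e-07, adjusted p = 0.0564 with an estimated correlation). Besides Ccl2, the chemokine gene Ccl7 rose by 5.58 ± 0.16 (1 of 3 Ctrl arrays above background), Myc by 4.21 ± 0.21, the lectin gene Clec10a by 2.56 ± 0.16 and Arg1 by 2.23 ± 0.19 (2 of 3). Of 36 interferon-stimulated genes 22 rose and 14 did not pass (22 rose and 1 fell adjusted over the list alone; camera adjusted p 7.22e-07, adjusted p = 0.297 with an estimated correlation), with the antiviral gene Rsad2 up by 2.58 ± 0.18. Of 24 inflammatory genes 9 rose (9 and 1 fall adjusted over the list alone; camera adjusted p 0.00361, adjusted p = 0.216 with an estimated correlation). Acod1 rose by 3.46 ± 0.16 and Il1b by 3.78 ± 0.24, the costimulatory gene Cd86 was at least 4.89-fold higher, and Nos2 differed by -0.11 ± 0.25 without passing. Of 34 NF-kB targets 18 rose and 1, Icam1, fell (20 and 1 adjusted over the list alone; camera adjusted p 6.61e-05, adjusted p = 0.297 with an estimated correlation), with Lcn2 up by 3.41 ± 0.15.

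Camera called lists of chemoattractants and of secreted factors in M. Of 26 ligands 12 rose and 1, Cx3cl1, fell (13 and 4 adjusted over the list alone; camera adjusted p 3.80e-05, adjusted p = 0.216 with an estimated correlation), and Csf3 rose by 3.86 ± 0.17. Of 28 receptors 12 rose, equally over the list alone, with a list median of 0.12 (camera adjusted p 0.00193, adjusted p = 0.297 with an estimated correlation). The sphingosine phosphate receptor gene S1pr1 was at least 5.58-fold higher and the complement receptor gene C5ar1 rose by 3.03 ± 0.24 (2 of 3 Ctrl arrays above background). Of 29 matrix proteases and inhibitors 12 rose and 3, Timp1, Adam10 and Adam17, fell (13 and 3 adjusted over the list alone; camera adjusted p 0.000253, adjusted p = 0.297 with an estimated correlation), including Plat by 3.87 ± 0.17. With only probes above background on all 9 arrays the call of the proteases ended (adjusted p 0.0887), as did that of the inflammatory genes under array weights (adjusted p 0.0687). Of 25 angiogenic and growth factors 11 rose and 3, Tgfb3, Tek and Ang, fell (13 and 4 adjusted over the list alone; camera adjusted p 0.000387, adjusted p = 0.297 with an estimated correlation). Areg rose by 5.50 ± 0.19 (2 of 3 Ctrl arrays above background) and the lymphatic growth factor gene Vegfc by 2.83 ± 0.16. Of 30 checkpoint and T cell suppression genes 14 rose (15 and 1 fall adjusted over the list alone; camera adjusted p 2.72e-05, adjusted p = 0.164 with an estimated correlation). Nt5e was at least 10.9-fold higher, Sirpa rose by 2.59 ± 0.18 and Cd274 by 1.91 ± 0.36. The Cd274 call ended in 2 of 25 other settings.

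Some macrophage genes were higher in M than in Ctrl, among them the sort markers Adgre1 by 2.86 ± 0.22 and Ptprc by 0.80 ± 0.20. The Ptprc call ended in 7 of 25 other settings, among them the fit of 2 groups and leaving out Ctrl1, Ctrl2, M1 or M3 (adjusted p up to 0.395). Of 19 pan-macrophage genes 8 rose (9 adjusted over the list alone; camera adjusted p 0.000601, adjusted p = 0.360 with an estimated correlation), and Csf1r differed by -0.19 ± 0.19 without passing. Of 19 large peritoneal macrophage genes 8 rose, equally over the list alone, with a list median of 0.05 (camera adjusted p 0.0271, adjusted p = 0.360 with an estimated correlation), Selp by 2.32 ± 0.17 (2 of 3 Ctrl arrays above background) and Cd93 by 2.09 ± 0.18. Of 15 MHC class II genes 6 rose (7 and 1 fall adjusted over the list alone; camera adjusted p 0.00942, adjusted p = 0.314 with an estimated correlation), with H2-Eb1 up by 2.56 ± 0.22. Of 34 scavenger and phagocytic receptors 12 rose and 2, Cd163 and Cd300ld, fell (12 and 3 adjusted over the list alone; camera adjusted p 0.00193, adjusted p = 0.297 with an estimated correlation), with the Fc receptor gene Fcgr3 up by 2.82 ± 0.25. Of 39 lysosome genes 8 rose and 1, Tfeb, fell, equally over the list alone (camera adjusted p 0.0106, adjusted p = 0.638 with an estimated correlation), and the cathepsin gene Ctsh rose by 3.95 ± 0.40. Of 25 other settings 4 ended the call of the large peritoneal genes, among them leaving out Ctrl3 and the deposited value table (adjusted p up to 0.221), and 3 each that of MHC class II (up to 0.183) and of the lysosome (up to 0.0767), among them both other filters on dim probes. Of 24 NRF2 oxidative stress targets 8 rose, equally over the list alone (camera adjusted p 0.00927, adjusted p = 0.434 with an estimated correlation), the quinone reductase gene Nqo1 by 4.87 ± 0.23.

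Of 32 immediate early genes 14 rose in M and 2, Fosb and Egr3, fell (19 and 2 adjusted over the list alone; camera adjusted p 2.72e-05, adjusted p = 0.297 with an estimated correlation). Fosl1 rose by 1.85 ± 0.19 and Rgs1 by 1.60 ± 0.19. Of 22 TGF-beta targets 10 rose and 2, Ltbp1 and Cdkn2b, fell (11 and 4 adjusted over the list alone; camera adjusted p 0.0312, adjusted p = 0.297 with an estimated correlation), a call that ended in 7 of 25 other settings, among them median scaling, the deposited value table and leaving out Ctrl3 (adjusted p up to 0.303). The ribosomal protein list was called lower with a median of -0.30, although only Rps25 of its 39 members fell, and 0 adjusted over the list alone (camera adjusted p 0.0150, adjusted p = 0.828 with an estimated correlation). Quantile normalization, median scaling and 5 other settings of 25 ended that call (adjusted p up to 0.640).

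Some granulocyte markers were higher in M than in Ctrl. Of 21 tested 9 rose, equally over the list alone, and camera called the list higher (adjusted p 0.00511, adjusted p = 0.314 with an estimated correlation) with a median of -0.01 and a mean of 1.03, which differ in sign. The calprotectin subunit gene S100a8 rose by 4.97 ± 0.22 and the stefin gene Stfa2 by 3.44 ± 0.21, and Mmp9 and Lcn2 stand on this list too. Leaving out Ctrl3 and 3 other settings of 25 ended the call (adjusted p up to 0.183). Of 9 platelet and erythroid markers 3 rose, the platelet chemokine gene Pf4 by 5.98 ± 0.35 and Gp9 by 2.11 ± 0.20, and 1, Ahsp, fell (3 and 2 adjusted over the list alone). The Ahsp call ended in 17 of 24 other settings, among them quantile normalization, median scaling and normexp (adjusted p up to 0.599). Of 17 carcinoma epithelium markers 2, Lcn2 and Areg, rose and 1, Lgals4, fell, equally over the list alone.

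In all, 2248 genes were higher and 2070 lower in M than in Ctrl (limma), of which 1260 and 1237 changed at least 2-fold, and the arrays did not overlap for 36.3% of genes, against 10% by chance. Of the unnamed probes 388 were higher and 886 lower. Ctrl and M shared a slide and scan, so a block for either cannot alter this comparison (2248 and 2070 with it). The fit still took part of its spread from the T arrays on the other slide, with a median SD of 0.17 against 0.31 in Ctrl. Fitting the arrays of the shared slide alone gave 1409 and 806, and kept 2178 of the 4318 calls. On the shared slide Ctrl1 and Ctrl2 lay in column 1, Ctrl3 and M2 in column 2, and M1 and M3 in column 3. Group and slide column thus largely coincide. In the pair M2 and Ctrl3, 96.1% of the genes called here had the sign of the fit. Their median absolute log2 difference was 0.57 in that pair, against 1.09 in the fit. An effect of position on the slide was not tested. Without Ctrl3 the counts were 4019 and 3919, whereas leaving out Ctrl1, Ctrl2, M1 or M3 gave between 1356 and 1481 higher and between 513 and 586 lower, and leaving out T2 gave 1302 lower. Of 96 named genes called here 29 lost their call in some other setting, 17 with the deposited value table and 13 with a single array left out, namely Acta2, Ahsp, Axl, Cap2, Cd3d, Lgals4, Pip5k1b, Pla2g2c, Ptprc, Tcf4, Tpm2, Tpsb2 and Vegfa. The share of calls that were higher was 52.1%, against 66.1% under quantile normalization and 74.3% under median scaling, and the median of all genes was -0.10, 0.04 and 0.20.

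**Figure D2:**
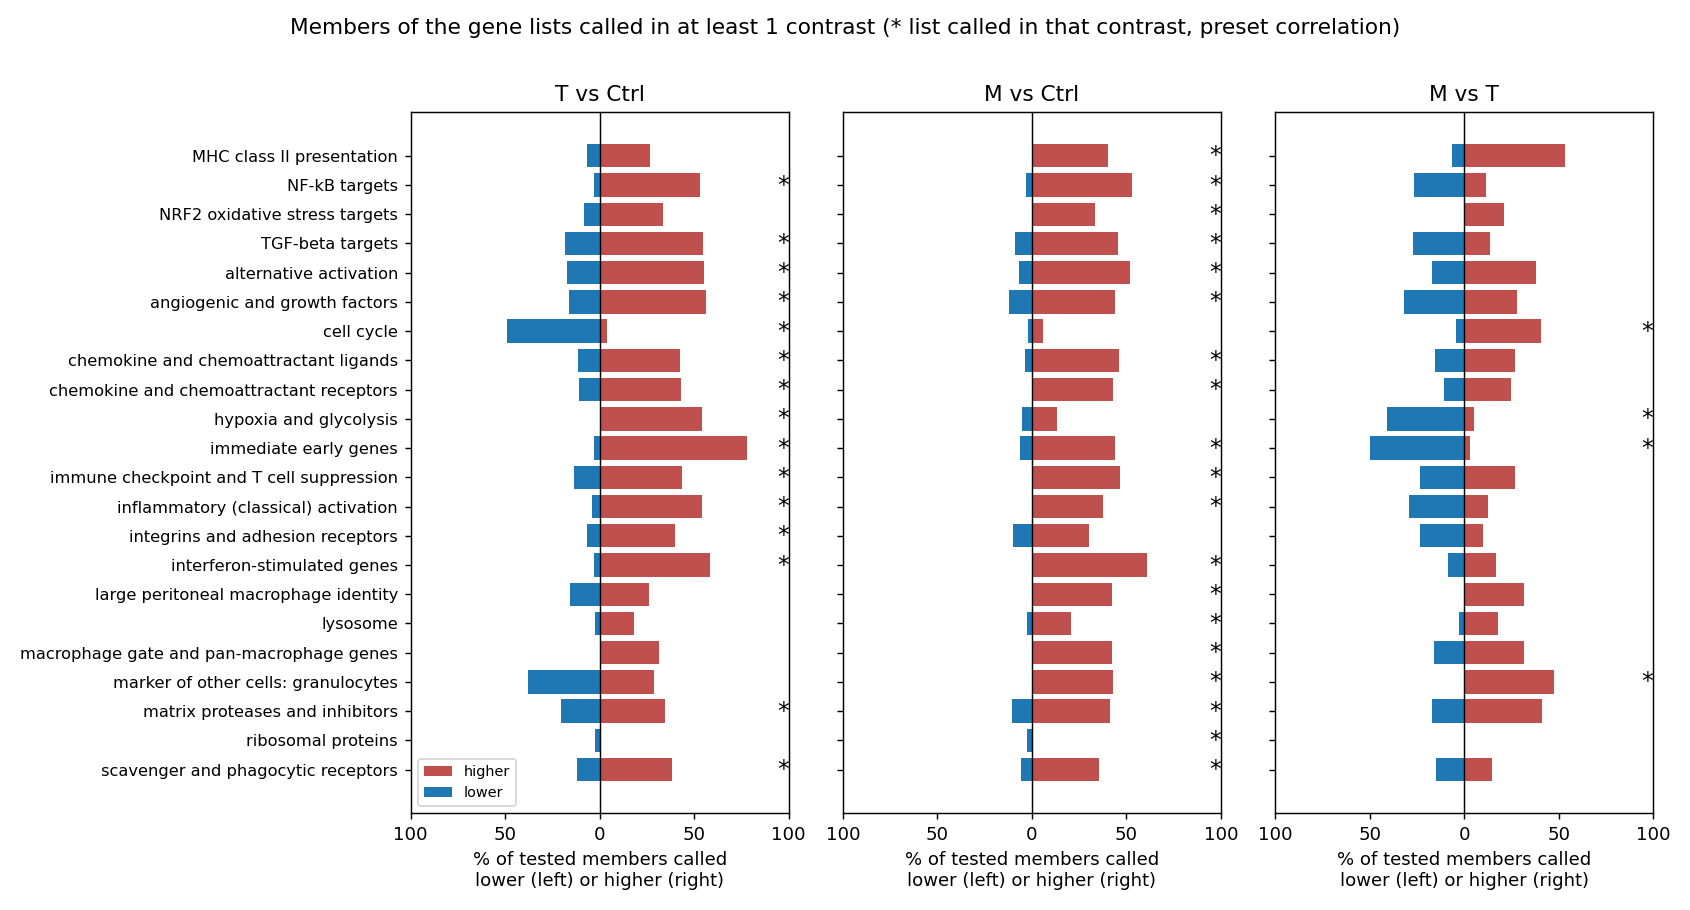
Share of the tested members of each list, in percent, called lower (left of 0) or higher (right of 0) in each of the 3 comparisons, for the lists that camera called in at least 1 of them, with an asterisk where it did at the preset correlation. Of 32 immediate early genes 25 were higher in T than in Ctrl, and 16 were lower in M than in T.

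The comparison of M with T asked how migratory macrophages differed from co-cultured macrophages of the lower chamber. The duration of the M co-culture is not given, so a difference in time cannot be told apart from migration, here or against Ctrl. The chamber also differed between M and T and cannot be told apart from migration either. Slc9b2 and Atp6v0d2 were at least 238-fold and 150-fold higher in M, and neither was well above background on any T array. Ctsk was higher by 8.88 ± 0.27 (470-fold, SE, n = 3 per group, 2 of 3 T arrays above background), and Tfec and Plpp3 at least 31.04-fold and 23.4-fold. Ppfibp2 was higher by 6.43 ± 0.27, Tmem121 at least 38.8-fold and Oaf at least 19.0-fold. On mm9 the Slc9b2 probe lies on chromosome 3 from 135005416 to 135005475. Serpinf1, which encodes the antiangiogenic secreted protein PEDF, was lower in M by -5.25 ± 0.20 log2 units (probe on chromosome 11 from 75223582 to 75223641), Hspb7 by -5.15 ± 0.20, Plek2 by -4.86 ± 0.21 and Pxdn by -4.78 ± 0.24. Steap1 and the lipid kinase gene Pik3c2g were at least 12.6-fold and 14.7-fold lower, and Tmem26 and Pip5k1b fell by 5.78 ± 0.25 and 4.89 ± 0.83 with 2 of 3 M arrays above background.

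The list of hypoxia and glycolysis genes was called lower in M than in T at the preset correlation. Of 37 tested 15 fell and 2, Pfkfb4 and Anln, rose (16 and 2 adjusted over the list alone), with a list median of -0.35 (camera adjusted p 1.74e-06, adjusted p = 0.650 with an estimated correlation). P4ha2 fell by 2.25 ± 0.19, Egln1 by 1.95 ± 0.22, the carbonic anhydrase gene Car12 by 1.70 ± 0.18 and Vegfa by 0.73 ± 0.16. Of 32 immediate early genes 16 fell and 1, Nr4a2, rose (17 and 2 adjusted over the list alone), with a list median of -0.65 (camera adjusted p 1.74e-06, adjusted p = 0.650 with an estimated correlation). Egr1 fell by 2.99 ± 0.37, Egr2 by 2.34 ± 0.19, Maff by 1.71 ± 0.17 and Ccn1 by 2.42 ± 0.22 (1 of 3 M arrays above background). Of 49 cell cycle genes 20 rose and 2, Cdk1 and Cdc6, fell (22 and 2 adjusted over the list alone), with a list median of 0.42 (camera adjusted p 0.000697, adjusted p = 0.735 with an estimated correlation). Prc1, a spindle midzone protein gene, rose by 1.63 ± 0.24, the phosphatase gene Cdc25c by 1.46 ± 0.20 and Kif20a by 1.11 ± 0.15. The calls of Kif20a and Ccn1 ended in 1 of 23 and 1 of 22 other settings.

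The granulocyte marker list was also called higher in M than in T, with 10 of 21 rising (11 adjusted over the list alone; camera adjusted p 0.00233, adjusted p = 0.650 with an estimated correlation) and a median of 0.81. The neutrophil collagenase gene Mmp8 rose by 2.97 ± 0.26, Mmp9 by 2.89 ± 0.16 and S100a8 by 1.91 ± 0.22. With the deposited value table the list was not called (adjusted p 0.794), nor were Mmp8 (0.0541), Mmp9 (0.662), S100a8 (0.854) or Stfa2 (0.563). Of the carcinoma epithelium markers Krt19 and Elf3 fell by 4.31 ± 0.27 and 1.54 ± 0.18, with Krt19 above background on 1 of 3 M arrays, whereas Epcam, Ocln, Lcn2 and Areg rose. Pf4 rose by 3.61 ± 0.35. The deposited value table ended the calls of Krt19 (adjusted p 0.0505), Elf3 (0.618), Areg (0.710) and Pf4 (0.278), and that of Epcam ended under normexp and without M1 and M3 (up to 0.218).

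Of the genes fixed in advance, Adgre1 was higher in M by 2.77 ± 0.22, Ptprc by 0.79 ± 0.20 (a call that ended in 7 of 23 other settings, adjusted p up to 0.271), Ccl2 by 3.19 ± 0.19 and Cd274 by 1.48 ± 0.36, and Arg1 fell by 1.71 ± 0.19. The call of Cd274 ended in 3 of 23 other settings, among them leaving out M3 (adjusted p up to 0.321), and those of Adgre1 (0.107) and Ccl2 (0.307) with the deposited value table. Csf1r, Cx3cr1, Cxcr4, Il10 and Nos2 differed by -0.08 ± 0.19, -0.50 ± 0.22, -0.19 ± 0.21, -0.22 ± 0.27 and -0.49 ± 0.25 and did not pass. Against Ctrl, Il10 rose by 1.55 ± 0.27 in T and 1.33 ± 0.27 in M, Cxcr4 by 1.72 ± 0.21 in M, and Vegfa by 0.52 ± 0.16 in M. The Il10 call ended in 1 of 23 other settings in T and in 3 of 25 in M. That Vegfa call ended in 15 of 25 other settings, among them normexp and leaving out any single array but Ctrl3 (adjusted p up to 0.260). Cx3cr1 rose by 0.73 ± 0.22 in T, a call that ended in 8 of 23 other settings, among them leaving out Ctrl1, Ctrl2, T1, T2 or T3 (adjusted p up to 0.372). It differed by 0.23 ± 0.22 in M without passing, and Csf1r differed by -0.11 ± 0.19 in T without passing. Mrc1, the mannose receptor gene, was well above background on 0 of 9 arrays and Ccr2 on 2, and neither was tested.

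In all, 2767 genes were higher and 1980 lower in M than in T (limma), of which 1344 and 1145 changed at least 2-fold, and 48.5% of genes had arrays that did not overlap, against 10% by chance. Of the unnamed probes 1434 were higher and 1204 lower. The share of calls that were higher was 58.3%, against 44.8% under median scaling, where the median of all genes was -0.01 in place of 0.12. With the deposited value table, whose T2 column matched no scanner file, 770 were higher and 667 lower, and 1638 and 1312 without that column. Of 64 named genes called here 42 lost their call in some other setting, 36 with that table and 7 with it but without that column. The 36 included Slc9b2 (adjusted p 0.0534), Ctsk (0.0795), Atp6v0d2 (0.0755), Tfec (0.166), Plpp3 (0.167), Tmem121 (0.0519), Ppfibp2 (0.0822), Oaf (0.228), Tmem26 (0.0604), Serpinf1 (0.0522), Pik3c2g (0.211), Hspb7 (0.119) and Pxdn (0.113), which kept their direction and passed without that column. Leaving out a single array ended the calls of 9, namely Acta2, Cd274, Cd79a, Cd79b, Eomes, Gzma, Il4, Ly6d and Ptprc. Leaving out M3, T2 or T3 gave 1833, 1667 and 1599 higher, and leaving out T2 gave 1306 lower. The F test over the 3 groups called 9464 genes (51.1%). Camera called 15, 19 and 4 of 39 lists in T against Ctrl, M against Ctrl and M against T, and 0 of them with an estimated correlation, where 6, 5 and 1 had an unadjusted p under 0.05.

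Many genes were called in the same direction in T and in M against Ctrl. In both comparisons 1323 genes were higher and 1314 lower, where independent lists of the same lengths would share 387 and 575. The fold changes correlated across genes at r = 0.62, and 74.6% had the same sign. Unchanged groups simulated against the same controls gave r = 0.50 and 66.6%, and the covariance was 0.554 against a simulated 0.0379. The simulation drew independent noise with 1 spread per gene for all groups. The real Ctrl arrays varied more (median SD 0.31, against 0.17 in T and 0.22 in M), so the simulated r, share of same sign and covariance may all be too low. A larger spread of the shared controls alone raises r and the share of same sign. These 2 values thus do not decide whether T and M shared a difference from Ctrl. Genes are not independent replicates, and 3 control arrays cannot be split into sets of 2, so part of the excess may come from the shared controls. Of the 2637 genes called in the same direction, 579 also differed between M and T, 247 with the larger change in M and 332 with the smaller. Csf3, Csf1, P4ha2 and Pgf were lower in M than in T while higher than in Ctrl, and Ctsk, Mmp9 and Ccl2 were higher in M than in T. Another 236 genes were called in opposite directions, between 104 (without Ctrl2) and 332 (without Ctrl3) with 1 array left out and 14 with the deposited value table. Without Ctrl1 or Ctrl2, 793 and 850 genes were higher in both and 202 and 195 lower in both, against 2507 and 3081 without Ctrl3.

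**Figure D3:**
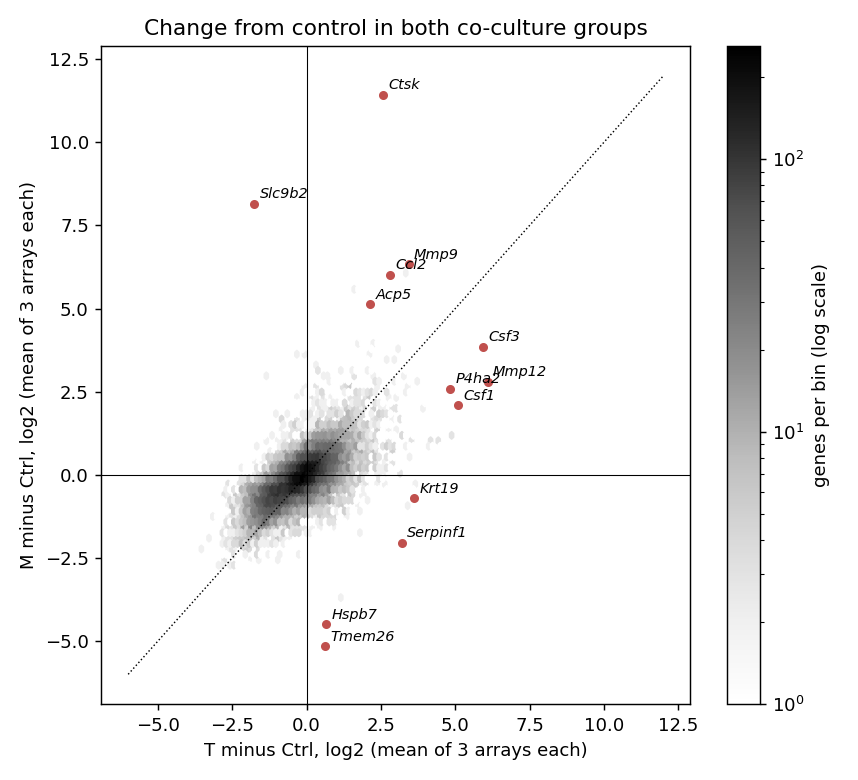
Log2 difference from Ctrl in T (horizontal) and in M (vertical) for the 18537 genes, as counts per bin on a log grey scale, with named genes as red points at their measured means, also where a group was not well above background, and a dotted line of equal change. Csf3 (5.92 in T, 3.86 in M) lies below that line, and Mmp9 (3.43 and 6.33) and Ccl2 (2.82 and 6.01) lie above it.

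Camera did not call the lists that follow in the comparison given. In T against Ctrl, 4 of 45 actin cytoskeleton genes rose and 4 fell, 8 of 25 cholesterol biosynthesis genes fell, and 8 of 34 unfolded protein response genes rose and 8 fell. Of 19 heat shock genes 5 rose and 3 fell, and of 13 small peritoneal macrophage and monocyte markers 3 rose and 2 fell. These numbers were the same adjusted over the list alone. Of 21 extracellular matrix genes 5 rose and 6 fell (5 and 7 adjusted over the list alone), of 32 LXR and lipid genes 7 and 5 (6 and 4), and of 15 complement genes 5 and 5 (5 and 7). The MHC class I genes Psmb10 and Pdia3 fell, and neither passed adjusted over the list alone. Of the lists called in M, 5 of 19 large peritoneal macrophage genes rose in T and 3 fell, 8 of 24 NRF2 targets rose and 2 fell, and 4 of 15 MHC class II genes rose and 1 fell, equally over the list alone. Of 39 lysosome genes 7 rose and 1 fell (4 rose adjusted over the list alone), and of 19 pan-macrophage genes 6 rose (camera adjusted p 0.0603). Among markers of other cells in T, 5 of 12 B cell markers fell, 2 of 19 mesenchymal markers rose and 6 fell, and 2 of 12 dendritic cell markers rose and 4 fell, equally over the list alone. Of 7 mesothelial markers 1, Krt19, rose and 3 fell (1 and 4 adjusted over the list alone). The mast cell and basophil list had 4 tested members, too few for a list test, with 2 rising and 2 falling.

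In M against Ctrl, the numbers rising and falling were 3 and 3 for actin cytoskeleton, 3 and 1 for cholesterol biosynthesis, 4 and 5 for the unfolded protein response, 2 and 1 for MHC class I, and 5 and 1 for small peritoneal macrophage markers, equally over the list alone. Extracellular matrix genes numbered 2 and 3 (2 and 4 adjusted over the list alone), LXR and lipid genes 6 and 3 (6 and 4), complement genes 7 and 2 (7 and 6) and integrins 9 and 3 (11 and 4). Of 37 hypoxia and glycolysis genes 5 rose and 2 fell, equally over the list alone, and of 49 cell cycle genes 3 rose and 1 fell (2 and 1). The heat shock gene Hspa4l rose and Serpinh1 fell, and of 36 oxidative phosphorylation genes only Sdhd fell, and none of these passed adjusted over the list alone. Of 18 T and NK cell markers 4 rose and 2 fell (6 and 2 adjusted over the list alone), 2 mesenchymal markers rose and 1 fell, 2 dendritic cell markers rose and 1 fell, and the B cell marker Bank1 and the mesothelial marker Efemp1 fell. In M against T, 7 of 25 cholesterol biosynthesis genes rose (8 adjusted over the list alone; camera adjusted p 0.0922), as did 4 of 15 complement genes (6 adjusted over the list alone; camera adjusted p 0.0504) and 5 of 18 T and NK cell markers (5 adjusted over the list alone). Of 34 unfolded protein response genes 5 fell, equally over the list alone (camera adjusted p 0.0922), and of 15 MHC class II genes 8 rose and 1 fell (8 and 2 adjusted over the list alone; list median 0.61; camera adjusted p 0.206). Of 24 inflammatory genes 3 rose and 7 fell (6 and 11 adjusted over the list alone), and of 29 alternative activation genes 11 rose and 5 fell (14 and 7).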

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

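The tests of the T2 column of the deposited value table were chosen after its mismatch with the scanner files had been seen. That column is data that no comparison of the report used as its main source. In it, 157 of the tested genes lay over 1 log2 unit above the highest of the 9 scanner arrays and 69 lay as far below the lowest, whereas single scanner arrays had between 3 and 126 genes that far above the other 8. The genes farthest above were inflammatory ones, with Cxcl3 5.53, Il1b 4.49, Saa3 4.19 and Il1a 3.55 log2 units above the highest array. Granulocyte markers had the largest share of such genes among the fixed lists (8 of 21, 38.1%). Of 2489 genes that changed at least 2-fold between M and T, 54.0% lay nearer the M mean in this column. Ctsk stood at 2.92 (M mean 3.12, T mean -5.76) and Tmem26 at -4.64 (M mean -5.17, T mean 0.61), whereas Csf1 stood at -0.49 (T mean -0.77, M mean -3.78).

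Only 0.198% of probes in the column equalled the T2 scanner signal up to a constant, against 100% for a column that matched, and Ctsk and Tmem26 stood near the M means, which argues against the T2 array under another scale or centring. At most 0.160% equalled any of the other 8 scanner arrays, which argues against a copy of one of them. A mixture of T and M RNA would keep genes within the range of those arrays, and 1.45% of tested genes lay over 1 log2 unit outside it, between the bounds of 1% and 5%, so a later test took the 72 genes at least 8-fold apart between M and T and above background on all 6 arrays, of which 66.7% needed under 25% T RNA and 4.17% over 75%, between its bounds of 1% and 10%. A mixture stays open by these tests, although it does not give the inflammatory genes far above all arrays, and the column may hold an array of another sample, which the files do not name. No biological explanation was tested.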

How the results depend on the processing

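The value table without its T2 column and the fits without M1 and M3, or without Ctrl1 and Ctrl2, were chosen after seeing the data, and the cause of a change was not tested unless given. Counts here are of genes higher, then lower. Quantile normalization left 731 genes lower in both T and M. Median scaling gave 5199 and 2701 in T against Ctrl, 1064 lower in M against Ctrl and 1625 higher in M against T, with 2151 higher in both, 604 lower in both and 119 opposite. Its centring moves all genes by 1 shift per array. Without a filter on dim probes 4030 were higher in M against Ctrl and 5424 in M against T, where 8 lists were called, with more genes tested. Fits of 2 groups gave 1409 and 806 in M against Ctrl, 456 lower in both and 128 opposite. Array weights gave 6301 and 8269, 5448 and 6133, and 5581 and 3389 in T against Ctrl, M against Ctrl and M against T, 15954 in the F test, and 3855, 4905 and 1109 in the overlap. Their estimation stopped before convergence, with a weight of 19.2 on Ctrl2 and 0.131 on Ctrl3, so they are no better estimate. The deposited table gave 1325 and 732 in M against Ctrl, 770 and 667 in M against T with 7 lists, 6100 in the F test, and 871, 475 and 14 in the overlap. Without its T2 column it gave 3376 lower in T against Ctrl, 1263 lower in M against Ctrl, 1638 and 1312 in M against T, 561 lower in both and 131 opposite, and Aknad1 turned to -1.11 in T against Ctrl. Without M1 and M3 the counts were 732 and 152 in M against Ctrl, 1369 and 1036 in M against T, and 495, 42 and 69 in the overlap. Without Ctrl1 and Ctrl2 they were 1606 and 1790 in T against Ctrl, 938 and 357 in M against Ctrl, 5986 in the F test, and 507, 85 and 59 in the overlap. In both, the lone array is assumed to vary like the other groups. With an estimated correlation camera called 0 lists in each comparison (unadjusted p under 0.05 in 6, 5 and 1).

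With the replicate number as a block the counts were 2967 and 5059, 2118 and 2422, and 2531 and 1784. Deviations of same-numbered arrays correlated at 0.547, 0.121 and 0.376 between T and Ctrl, but at -0.268, -0.187 and 0.0159 between M and Ctrl and -0.272, -0.145 and 0.0243 between M and T, so the numbers were not taken to pair the samples, and the block moved no count by over 1.5 times. Slide or scan as a block gave 2248 and 2070 in M against Ctrl, which the shared slide fixes. Normexp, the stricter filter, the mean of probes and a trended, robust variance moved no count of genes by over 1.5 times.

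Leaving out 1 array gave 2303 to 4280 and 3322 to 5631 in T against Ctrl, 1356 to 4019 and 513 to 3919 in M against Ctrl, 1599 to 3803 and 1306 to 2468 in M against T, and 6567 to 11804 in the F test. Lists called numbered 14 to 16, 17 to 22 and 4 to 6. The overlap ran from 793 to 2507 higher in both, 195 to 3081 lower in both and 104 to 332 opposite. Moves over 1.5 times in T against Ctrl were 3426 lower without T2 and 3322 without T3. In M against Ctrl they were 1377 and 586 without Ctrl1, 1414 and 540 without Ctrl2, 4019 and 3919 without Ctrl3, 1481 and 555 without M1, 1356 and 513 without M3, and 1302 lower without T2. In M against T they were 1833 higher without M3, 1667 and 1306 without T2, and 1599 higher without T3. In the overlap, higher and lower in both were 793 and 202 without Ctrl1, 850 and 195 without Ctrl2, 2507 and 3081 without Ctrl3, and 875 and 224 without M3, with 222 lower without M1, 585 without T2 and 677 without T3. Opposite calls numbered 122 without Ctrl1, 104 without Ctrl2, 147 without M1, 138 without M3, 135 without T2 and 132 without T3. Aknad1 ranged from -1.42 to 7.11 and turned to -1.33, -1.12 and -1.42 without T1, T2 and T3, where another of its probes was the brightest tested.

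No called list turned direction. Without Ctrl3 the calls of ligands in T against Ctrl and of large peritoneal genes, TGF-beta targets and granulocyte markers in M against Ctrl ended. The ribosomal call ended without Ctrl1 or M1, the integrin call without T1, and the protease call in T against Ctrl without Ctrl2, Ctrl3, M2 or T1. Of 279 results for named genes 268 kept their call and direction under quantile normalization, 262 under median scaling, 258 under normexp and 215 with the deposited table. Signal over background limits dim genes, most on M1, where 60.5% of probes were well above it.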

Other observations

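The tests of the osteoclast-associated genes, and the slide test and the test without both Ctrl1 and Ctrl2 of the dim genes, were chosen after the results had been seen, and the other tests of dim genes and the splits of the samples before.

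Among the 236 genes called in opposite directions in T and M against Ctrl, 143 were higher in T and lower in M, and 93 were the reverse. The count ran from 104 to 332 with 1 array left out, moved over 1.5 times without Ctrl1, Ctrl2, M1, M3, T2 or T3, and was 14 with the deposited value table. All 9 arrays were above background for 169 of them, and the arrays of both comparisons did not overlap for 227. The genes named here were chosen after their values were seen. Serpinf1, which encodes an antiangiogenic secreted protein, was higher by 3.20 ± 0.20 log2 units in T and lower in M, where it fell by 2.04 ± 0.20. Dntt, a DNA polymerase of lymphocyte development, rose by 2.58 ± 0.17 in T and fell by 1.39 ± 0.17 in M, and the cytokine gene Lta rose by 1.27 ± 0.21 and fell by 1.90 ± 0.21. In the other direction, Fam13a fell by 1.08 ± 0.30 in T and rose by 3.42 ± 0.30 in M, and the protease inhibitor gene Timp2 fell by 1.29 ± 0.27 and rose by 1.80 ± 0.27. Mmp8 fell by 1.03 ± 0.26 in T and rose by 1.93 ± 0.26 in M, and the complement protease gene C1ra fell by 1.38 ± 0.21 and rose by 1.56 ± 0.21.

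The share of a list that could be measured differed between lists. Of 27 large peritoneal macrophage genes on the array 17 were well above background on all 9 arrays and 7 on none, namely Timd4, Tgfb2, Vsig4, Cxcl13, Fn1, Naip1 and Serpinb2. In contrast 49 of 50 cell cycle genes and 37 of 38 hypoxia and glycolysis genes were above on all 9 arrays.

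A hypothesis from the largest changes is that M macrophages may show osteoclast-like gene activity, since cathepsin K, the proton pump subunit Atp6v0d2, Slc9b2, Tfec and Mmp9 are osteoclast-associated. In a list of 25 such genes written after these 5 were noticed, 10 were higher and 1 lower in M than in Ctrl, with a median of 0.58, and the acid phosphatase gene Acp5 rose by 5.14 ± 0.26. The lower one was Cd109 (-1.56 ± 0.27), and 14 were not called, among them Dcstamp, Ocstamp, Calcr, Itgb3, Tnfrsf11a, Car2 and Src. In T against Ctrl 8 of the 25 were higher and 7 lower. Acp5 (2.15), Mmp9 (3.43) and Ctsk (at least 1.57-fold) were among the higher, so a rise of these was not particular to M. Without the 5 genes noticed first, 5 of 20 rose and 1 fell in M against Ctrl, and camera with an estimated correlation gave p = 0.0823, so the list beyond the noticed genes does not decide the hypothesis. All M and Ctrl arrays lay on 1 slide and scan, which excludes a difference between slides as the source (an earlier form of this test asked for a list median of at least 1, which 0.58 did not reach). High background of the M arrays was examined in M2 and Ctrl3, which shared a slide column and had negative controls of 32.4 and 36.4. The 14 members called higher without that pair were all higher in it, from 0.01 for Mitf to 11.02 for Ctsk, with a median of 2.34 (an earlier form over all 25 genes gave 0.49, under the bound of 1). That median includes the 5 genes noticed first, which had been picked for being high in M. Among the others Acp5, Nfatc1, Oscar and Mst1r exceeded 1 (4.82, 2.75, 1.94 and 1.23). Clcn7, Tcirg1, Dcstamp, Ostm1 and Mitf did not (0.87 to 0.01), so this pair does not decide. In each of the 10 called members the lowest M array exceeded the highest Ctrl array by more than 35.0 signal units, the widest gap in negative controls. The smallest excess was 49.6 for Mst1r, so background alone is argued against for those members. Another cell type in the sort was not tested.

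In the fifth of genes with the dimmest probes (3708), 79.0% of the calls in T against Ctrl were lower, against 67.2%, 44.6% and 39.1% in the groups of rising brightness between and 61.4% in the fifth with the brightest. Normexp gave 77.9%, but it is itself a background correction, so background subtraction stays open. The 2 Ctrl arrays of low background stay open too, with at least 76.8% when either was left out. Without both, 1 Ctrl array remained, too few to decide. Scaling stays open: quantile normalization gave 59.1%, which met the bound of 60% written beforehand, but it evens out distributions whatever their cause, and median scaling, added to the reading afterwards, gave 66.7%. M and Ctrl shared a slide, and there 68.6% of the calls among the dimmest genes were lower in M. The shares in the groups of rising brightness were 53.7%, 36.7%, 29.6% and 46.2%. A difference between slides does not give this pattern in M, but the filter may add to it. Dim genes were tested where a group was well above background, and Ctrl1 and Ctrl2 had the highest shares of such probes. Without the filter 4030 genes were higher and 2137 lower in M over all genes, against 3068 and 5970 in T. The share among the dimmest genes was not computed without it. The pattern in M thus does not decide on a slide effect in T. Of the T arrays 0 lay on the slide of Ctrl. Slide and a biological difference between T and Ctrl could thus each add to the share in T and cannot be told apart.

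Splits of the samples other than the real one were fitted for each comparison. For T against Ctrl, M against Ctrl and M against T, 1 of the 10 splits of the 6 arrays, the real one, gave as many calls (8346, 4318 and 4747), and the highest of the others gave 0 with limma. At an unadjusted p under 0.05 the real splits gave 9856, 7506 and 7092 genes and the highest others 3495, 3899 and 1176. These splits are too few for a share under 0.05. For the F test 1 of 100 splits drawn from 280 gave as many genes, the real one with 9464, and the highest other gave 4672. A random assignment of these arrays to groups thus did not reach that count. The arrays of a group may come from 1 culture, so chance differences between cultures are not excluded. Nor is a slide effect, since T alone lay on its slide.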
